A study of Mus musculus with 3 samples.

How the data were processed

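Gene expression was measured in sorted splenic follicular regulatory T (Tfr) cells on 3 single-colour Affymetrix arrays of 45101 probe sets. Per the labels, 1 array held RNA from a wild-type (WT) pool of 4 mice, and 2 arrays held RNA from Rptor-null pools of 8 mice each, labelled as biological replicates. The groups and replicate numbers were taken from the sample titles. Biotin-labelled cRNA was prepared from TRIzol-extracted total RNA by the standard protocol of the array maker, per the labels' protocols.

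The deposited values were probe-set intensities on a linear scale, which the authors had scaled or normalized before deposit. The submitters' processing notes list MAS5 without a version. Beyond that name, the background correction, the scaling target and the summary method were not described in the sources used here. The median intensity was 52.8 on the WT array and 55.0 and 54.9 on the Rptor-null arrays, and low values agreed closely between arrays, so the values were treated as scaled intensities and not tied to 1 summary method. For arrays, no count gives the depth, and the number of arrays limits the precision.

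Probe sets were named through the platform annotation: 34945 named 1 gene, 932 named several and 9160 were unnamed here, beside 64 control probe sets. No gene was named from a probe set with several symbols. Intensities were converted to log2(intensity + 16), so that each fold given is on that scale and understates the change of dim genes. Control probe sets were set aside, and probe sets at or below the 40th percentile of the mean of the 2 group means were left out, a level of 34.8 intensity units, which kept 27022 probe sets. The probe set with the highest mean level stood for a gene, giving 12725 genes. Of the 5641 genes with 2 or more kept probe sets, 2871 had all of them on the same side of WT.

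Differences between Rptor-null and WT were fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend). The tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over the 12725 genes, with a threshold of 0.05. With 1 WT array, the only residual degree of freedom (1, beside 6.46 prior degrees of freedom) came from the 2 Rptor-null arrays, and the WT array was assumed to vary like them. Genes at least 2-fold apart from WT in both Rptor-null arrays were counted without a test. The same count was made with each Rptor-null array in turn as the lone array.

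A set of 25 gene lists was tested with camera on the same fit, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Beside each list stand the counts of members past the test over all genes and adjusted over the list alone. The 13 list calls made with the preset correlation were all lost with a correlation estimated from the residuals, where the adjusted p was 0.58 for each of them. That estimate rests on 1 degree of freedom. The test, the lists, the genes to be named and 14 alternatives were fixed before the data were examined. The fixed alternatives were 2 other pseudocounts, 2 other filters, 2 other scalings, 2 other treatments of a gene's probe sets, 2 other variance priors, 2 arrays left out in turn, the estimated correlation, and 10000 random lists matched on level.

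How list symbols were matched to the annotation had not been fixed in advance. A first exploratory fit of the same design matched symbols exactly and called 14 lists. The matching used here also takes a unique older name and calls 13. It added 2 members over all lists, 1 of them to the B cell list, whose adjusted p went from 0.0419 to 0.126. The choice was therefore made after results had been seen, and exact matching was kept as an added alternative. A second added alternative left out probe sets that can match several transcripts. The marker lists for macrophages, basophils, neutrophils, dendritic cells and Y-linked genes in the closing section were also written after results had been seen.

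Named genes followed a fixed rule: Rptor and 16 other genes chosen for Tfr biology, the 10 largest increases and decreases past the test, and up to 4 members of each list with the largest smaller-of-2 difference on the same side of WT in both Rptor-null arrays. Provisional names, receptor variable segments and sex-linked genes were not named under the second part. Tcf7, 1 of the fixed genes, was not analysed here.

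The fit was tested on simulated data: 20 sets of 3 arrays with 12725 genes, of which 200 changed. It recovered 81.1% of log2 changes of 1 and 12.05% of log2 changes of 0.5, and 10.5% of its calls were false, above the nominal share of 0.05. In 20 sets with no change the median number of calls was 0 and the highest was 18, and at most 4 genes were 2-fold apart in both arrays. A list shifted by -0.5 was called in all 20 sets. These sets were drawn with the spread seen between the Rptor-null arrays, so they do not test the assumption about the WT array.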

Results

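Tfr cells are Foxp3-expressing T cells that enter B cell follicles and restrain the germinal centre reaction. They were sorted from the spleens of C57BL/6 mice 8 days after immunization with OVA, from lineage-depleted cells stained for CD4, CD44, GITR, CD25 and CXCR5. The study compared WT cells with cells of mice carrying CD4-Cre and a floxed Rptor gene. Rptor encodes raptor, the defining subunit of the kinase complex mTORC1, so the comparison asks how expression in Tfr cells differs when T lineage cells lack it. The WT group was 1 pool of 4 mice and the Rptor-null group 2 pools of 8 mice each, with 1 array per pool. WT values therefore have no replicate error, and Rptor-null values are given as mean ± SD (n = 2). Across genes, which are not independent replicates, log2 intensities correlated at 0.994 between the Rptor-null arrays and at 0.980 and 0.979 between each of them and WT.

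Rptor itself read 365 in WT and 353 and 412 in the Rptor-null pools, a log2 difference of 0.059 ± 0.14 (SE; adjusted p = 0.824). The probe set is not known to lie in the deleted part of the gene, so this value checks nothing about the deletion. RNA measures differed between the groups. The ratio of 3' to 5' signal was 1.11 in WT and 1.94 and 2.58 in the Rptor-null arrays for Gapdh, and 1.40, 2.65 and 2.87 for beta-actin. Xist, the X-inactivation transcript, read 6691 in WT and 1415 ± 385 in Rptor-null pools (log2 difference -2.26, adjusted p = 0.00286), and the sexes of the pooled mice were not given. No batch was given in the labels.

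**Figure D1:**
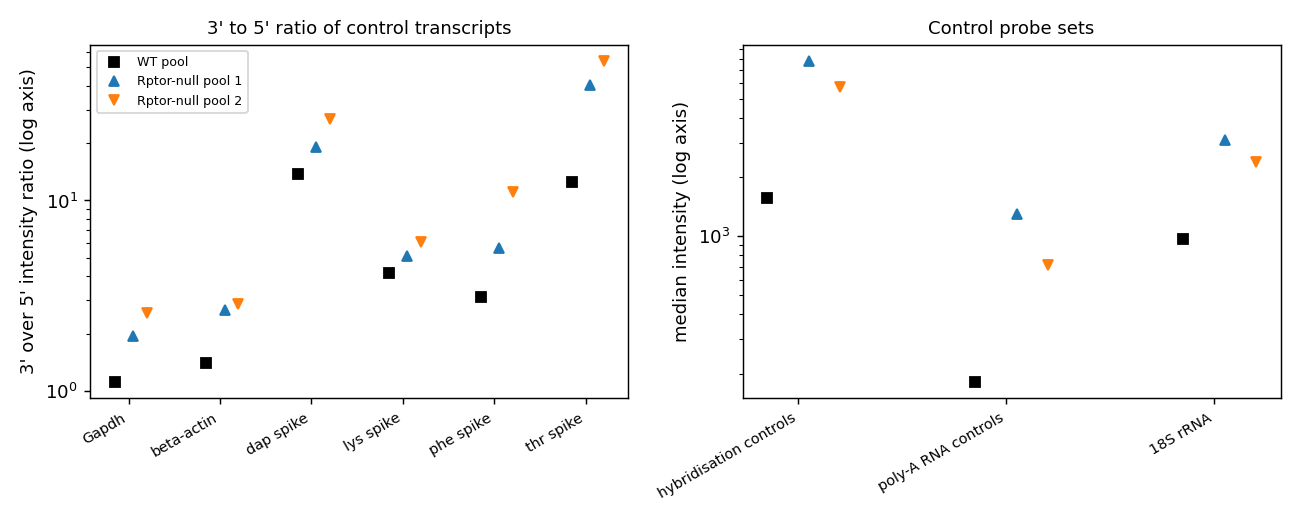
Ratio of 3' to 5' intensity for Gapdh, beta-actin and 4 spiked transcripts (left, log axis) and median intensity of control probe sets (right, log axis) on the WT array (squares) and the 2 Rptor-null arrays (triangles). Both Rptor-null arrays lie above WT for every control, with a Gapdh ratio of 1.94 and 2.58 against 1.11.

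The largest increase in the Rptor-null pools was that of Gdpd3, a phosphodiesterase of lipid metabolism, from 123 in WT to 1518 ± 135, or 11.02-fold (adjusted p = 0.000105). Cdh1, which encodes E-cadherin, rose 3.80-fold and Sema6d, a semaphorin, 3.05-fold. Ms4a2, the beta chain of the high-affinity IgE receptor, rose 2.99-fold, and Csf2rb2, a receptor subunit for interleukin 3, rose 2.97-fold. Adamdec1, Apobec1, Slc45a3 and Rpl27a rose between 2.73-fold and 2.91-fold. Pik3cd, a catalytic subunit of PI3 kinase, rose 2.93-fold on its brightest probe set, while its 5 kept probe sets ranged from -1.18 to 1.55 on the log2 scale and their mean was -0.029. Among these 10 largest increases 2 were basophil markers. The basophil and macrophage marker lists of the closing section had median log2 differences of 0.80 and 0.72. Which cells in the pools expressed these genes was not tested.

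After that of Xist, the largest decrease was that of Il1r2, a decoy receptor for interleukin 1, from 649 in WT to 138 ± 8.62 in Rptor-null cells, 4.33-fold lower (adjusted p = 0.0017). Npas4, an activity-induced transcription factor, was 3.45-fold lower, the phosphatase Dusp14 3.22-fold, Ncmap 3.15-fold and Gucy1a1 3.09-fold. Itgb8, an integrin subunit that activates TGF-beta, was 2.83-fold lower, and Fdps, an enzyme of isoprenoid synthesis, 2.68-fold. Ccnb2, Ube2c and Cdk1, which act in mitosis, were 3.03-fold, 3.03-fold and 2.68-fold lower.

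With limma and Benjamini-Hochberg adjustment, 500 genes were higher and 1409 lower in Rptor-null cells among 12725 tested. At least 2-fold differences in both Rptor-null arrays were found for 50 genes higher and 74 lower, and 0 genes met this rule with either Rptor-null array as the lone one. That 0 shows only that the 2 Rptor-null arrays resembled each other. Both differences in the main count share the 1 WT array, so a deviation of that array alone would also raise it. Without the first Rptor-null array, so that only 1 had to pass, the 2-fold counts were 117 higher and 126 lower. They were 31 and 36 with a pseudocount of 64, and 79 and 47 after quantile normalization, which turned the balance, while 27 were higher with the mean of a gene's probe sets. After quantile normalization the calls were 524 higher and 695 lower, after median centring 877 and 1594, and without a variance trend 300 and 770. In 5 bins of 2545 genes, from dim to bright, the median log2 difference was 0.077, -0.00175, -0.137, -0.155 and -0.124. This offset between the arrays was not removed before the test. The excess of lower calls and the list medians include it. In simulated sets 10.5% of calls were false, and of the 906 called genes with several kept probe sets 606 had all of them on the same side.

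Genes of the regulatory T cell core were lower in Rptor-null cells, with 13 of 32 measured members down, 0 up and 19 not past the test. Tnfrsf18, which encodes the sort marker GITR, fell from 3837 to 1501 ± 67.4, or 2.54-fold (adjusted p = 0.0017). Nrn1 was 2.32-fold lower, and Ctla4, an inhibitory receptor, was 2.00-fold lower (4713 against 2347 ± 195). Nt5e, the ectoenzyme CD73, was 2.04-fold lower on its brightest probe set, and its call was lost with the mean of its 3 probe sets. Il10 read 376 in WT and 222 ± 30.9 in Rptor-null cells (adjusted p = 0.0259), a call lost after quantile normalization. Foxp3, the lineage transcription factor, read 752 and 505 ± 116 (log2 difference -0.58, adjusted p = 0.0789). It passed the test with the 60th percentile filter and after median centring. Il2ra, which encodes the sort marker CD25, read 464 and 357 ± 12.6 (adjusted p = 0.102).

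The median log2 difference of this list was -0.53 (camera adjusted p = 2.77e-06; adjusted p = 0.58 with an estimated correlation), and 19 members were lower when adjusted over the list alone. On the same arrays the Gapdh 3' to 5' ratio was 1.11, 1.94 and 2.58, T cell identity genes had a median of -0.32 and myeloid markers one of 0.39.

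The Tfh and Tfr programme, genes shared by follicular helper and follicular regulatory cells, had 15 members lower, 3 higher and 14 not past the test among 32. Pdcd1, which encodes PD-1, fell 2.46-fold (654 to 257 ± 5.74). Icos, a costimulatory receptor, fell 2.22-fold (4733 to 2125 ± 81.8), Sostdc1 2.63-fold and the cytokine gene Il21 2.09-fold. Cxcr5, the receptor for follicle homing and 1 of the sort markers, was 1.83-fold lower (713 against 383 ± 12.8, adjusted p = 0.0062). The 3 higher members were Il6ra, Dusp6 and Cxcr4, with log2 differences of 0.99, 0.69 and 0.60. Bcl6, the transcription factor of follicular T cells, read 598 and 535 ± 7.35 (adjusted p = 0.426). Stat3 read 1336 and 1285 ± 38.3 (adjusted p = 0.756), with a direction that turned after quantile normalization.

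The list had a median of -0.43 (camera adjusted p = 0.00205; adjusted p = 0.58 with an estimated correlation), and 17 members were lower and 4 higher adjusted over the list alone. The shifts of the T cell identity genes (-0.32) and the myeloid markers (0.39) and the higher 3' to 5' ratios stood on the same arrays. Among the other fixed genes, Prdm1 (343 against 260 ± 9.49, adjusted p = 0.112), Myc (299 against 244 ± 12.8, adjusted p = 0.239) and Cd4 (696 against 583 ± 5.30, adjusted p = 0.19) did not pass. Cd44 read 3540 in WT and 4345 ± 54.1 (adjusted p = 0.0546) and passed with the 60th percentile filter and both other scalings.

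**Figure D2:**
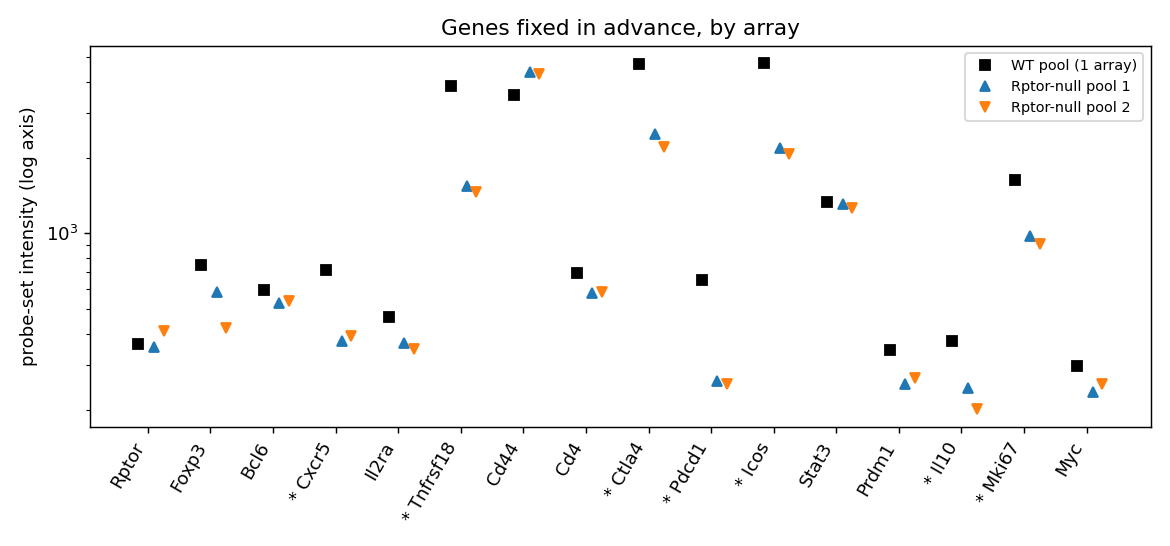
Probe-set intensity (log axis) of the genes fixed in advance on the WT array (square) and the 2 Rptor-null arrays (triangles), with an asterisk where the limma adjusted p was under 0.05. Tnfrsf18, Ctla4, Pdcd1, Icos, Cxcr5, Il10 and Mki67 lie lower in both Rptor-null pools and carry an asterisk.

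Cell cycle genes moved most among the lists. In the G2/M list, genes used in mitosis, 29 of 31 members were lower, 0 higher and 2 not past the test, and 11 were at least 2-fold lower in both arrays. Ccnb2, a mitotic cyclin, fell from 705 to 222 ± 6.24 (3.03-fold), Ube2c from 1301 to 419 ± 32.9 (3.03-fold), Birc5 from 645 to 235 ± 27.7 (2.64-fold) and Bub1 from 277 to 99.5 ± 0.64 (2.54-fold). Mki67, a marker of cycling cells, fell 1.72-fold (1632 to 941 ± 53.1, adjusted p = 0.00552). In the G1/S and replication list 21 of 30 members were lower, 0 higher and 9 not past the test. Rfc3 fell 2.51-fold, Tk1 2.45-fold, Prim1 2.13-fold and the DNA ligase Lig1 1.80-fold.

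The median log2 difference was -1.004 for G2/M (camera adjusted p = 1.62e-16) and -0.63 for G1/S (adjusted p = 1.4e-08), and for each the adjusted p was 0.58 with an estimated correlation. Adjusted over the list alone, 30 and 23 members were lower. The 3' to 5' ratio of beta-actin was 1.40, 2.65 and 2.87 on these arrays, and the medians of T cell identity genes and myeloid markers were -0.32 and 0.39.

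Oxidative phosphorylation genes were lower in 22 of 43 cases, with 0 higher and 21 not past the test. Atp5g1 and Atp5b, subunits of ATP synthase, fell 1.76-fold and 1.62-fold, and Sdhd, of succinate dehydrogenase, fell 1.72-fold (1872 to 1080 ± 2.20). The amino acid and one-carbon list had 7 of 26 members lower and 1 higher, with Psat1, of serine synthesis, 1.92-fold lower. In the MYC and ribosome biogenesis list 6 of 31 were lower and 0 higher, among them Nop16 (1.79-fold) and the nucleolar methyltransferase Fbl (1.48-fold). The medians were -0.35, -0.27 and -0.24 (camera adjusted p = 3.38e-10, 0.0134 and 0.0027), each with an adjusted p = 0.58 with an estimated correlation. Adjusted over the list alone, 30, 9 and 6 members were lower, with 2 higher in the second list. The higher 3' to 5' ratios, the lower T cell identity genes (-0.32) and the higher myeloid markers (0.39) accompanied these shifts.

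Other metabolic lists did not pass as groups. Among glycolysis genes 6 of 20 were lower and 2 higher: Tpi1 fell 1.78-fold and Hif1a, a transcription factor of the hypoxia response, fell 1.37-fold, while Hk2 rose 1.46-fold (list adjusted p = 0.17). Among sterol and fatty acid genes 4 of 29 were lower and 0 higher, led by Fdps and by Ebp at 1.94-fold (adjusted p = 0.241). In the mTOR pathway list 2 of 28 members were higher and 3 lower. Ddit4, an inhibitor of mTORC1 induced by stress, rose 2.09-fold (628 to 1337 ± 178) and Deptor 1.64-fold, while the cap-binding factor Eif4e fell 2.27-fold and Rraga 1.63-fold. Its median was -0.089 (0.0090 after quantile normalization) and its mean -0.039, with the camera direction up (adjusted p = 0.668). The 26 cytosolic ribosomal protein genes had 3 lower and 0 higher (adjusted p = 0.44), of which Rps9 and Rpl27 turned direction with the mean of their probe sets. Rpl27a, a ribosomal protein gene that this list does not hold, rose 2.73-fold. Adjusted over the list alone, the higher and lower counts were 2 and 9 for glycolysis, 0 and 5 for sterol synthesis, 2 and 4 for mTOR and 0 and 3 for ribosomal proteins.

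Interferon-stimulated genes were lower in 15 of 29 cases, with 0 higher and 14 not past the test. Usp18, a brake on interferon signalling, fell 2.29-fold (1196 to 514 ± 41.4), and the antiviral genes Oas1a, Ifit1 and Ifit3 fell 1.88-fold, 1.87-fold and 1.77-fold. The median was -0.45 (camera adjusted p = 8.61e-08; adjusted p = 0.58 with an estimated correlation), with 18 lower adjusted over the list alone. Immediate-early genes had 8 of 29 members higher and 2 lower. Egr1, a transcription factor induced by stimulation, rose 1.58-fold (7170 to 11365 ± 474) and the heat shock gene Hspa1a 1.54-fold, while Egr3 fell 1.61-fold on its brightest probe set. The Egr3 call was lost with the mean of its 2 probe sets. That list had a median of 0.066 (camera adjusted p = 0.00128; adjusted p = 0.58 with an estimated correlation), with 10 higher and 2 lower adjusted over the list alone. Without the second Rptor-null array the median was 0.114. The 3' to 5' ratios and the myeloid markers (0.39) were higher on the same arrays as both shifts.

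The lysosome and autophagy list had 6 of 31 members higher and 1 lower, the same numbers adjusted over the list alone. Lamp1, a lysosomal membrane protein, rose 1.60-fold (2993 to 4793 ± 15.2), Hexa, a lysosomal enzyme, 1.52-fold and Mitf, a transcription factor of the TFEB family, 1.51-fold, while Gabarapl2 fell 1.71-fold. The median was 0.13 (camera adjusted p = 0.00205; adjusted p = 0.58 with an estimated correlation), beside the myeloid marker median of 0.39 and the higher 3' to 5' ratios. It was 0.081 without the second Rptor-null array and 0.203 without the first.

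No call was made for the remaining T cell programmes. Among effector T helper genes Cxcr6, Cxcr3 and Ccr6 fell 2.41-fold, 1.95-fold and 1.75-fold and Ahr rose 1.36-fold, with 2 higher and 3 lower of 20 (adjusted p = 0.454). Cytotoxic genes had 4 higher and 2 lower of 21, Ccl4 rising 1.88-fold and Gzmk falling 1.99-fold; the median was 0.038, the mean -0.018 and the camera direction up (adjusted p = 0.325). That median fell below 0 with either Rptor-null array left out (-0.036 and -0.016) and with the mean of probe sets (-0.028). Quiescence and homing genes had 3 higher and 2 lower of 21, Satb1 rising 1.38-fold and Cd27 falling 1.77-fold (adjusted p = 0.146), and the list passed with the 60th percentile filter and after quantile normalization. Cytokine and STAT genes had 4 higher and 1 lower of 30, with Il6ra up 1.98-fold and Il21r down 1.67-fold; the median was -0.044, the mean -0.027 and the camera direction up (adjusted p = 0.592). Both other scalings turned that median, to 0.067 after quantile normalization and 0.0087 after median centring. Apoptosis genes had 0 higher and 3 lower of 24, 1 of them Birc5, which the G2/M list also holds; the median was 0.021, the mean -0.080 and the camera direction up (adjusted p = 0.65). It turned to -0.0088 without the first Rptor-null array, -0.010 without the filter, -0.018 with the mean of probe sets and -0.0066 without cross-matching probe sets. Without a variance trend the calls of Ahr and Satb1 were lost, as were those of Hk2, Hif1a, Rraga, Fbl and Bank1 in other lists. Adjusted over the list alone, higher and lower counts in these 5 lists were 2 and 4, 5 and 3, 4 and 2, 4 and 2, and 0 and 5.

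Markers of cell types other than the sorted one were measured as a check of the gate. Several cytotoxic and NK-type genes were bright in the WT pool itself: Gzma read 11301, Nkg7 2882 and Klrd1 2348, while Cd8a read 46.5. Which cells expressed them was not tested, and levels of different probe sets do not give cell shares. The check therefore does not show that the WT pool was free of other cells. Myeloid and dendritic cell markers were higher in 14 of 29 cases, with 0 lower and 15 not past the test. Adgre1, the macrophage antigen F4/80, rose 1.88-fold (602 to 1150 ± 145), the endotoxin coreceptor Cd14 1.87-fold, and the Fc receptor genes Fcgr2b and Fcgr3 1.84-fold and 1.79-fold. The 4 kept probe sets of Fcgr2b ranged from -0.015 to 0.88 on the log2 scale. Of 4 further members chosen after their values were seen, Siglech read 57.3 and Itgam 71.5 in the WT pool, Csf1r read 7911 there and 13736 ± 1651 in Rptor-null pools, and Lyz2 14972 and 16733 ± 989 (adjusted p = 0.251). The median was 0.39 (camera adjusted p = 2.65e-12; adjusted p = 0.58 with an estimated correlation), with 19 higher adjusted over the list alone, on arrays with a beta-actin 3' to 5' ratio of 1.40, 2.65 and 2.87. Without the first Rptor-null array it was 0.56.

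T cell identity genes were lower in 9 of 19 cases and 1, Ets1, was higher. Cd3g and Cd3d, subunits of the T cell receptor complex, fell 1.94-fold (9143 to 4704 ± 66.3) and 1.60-fold, and the adaptor Lat fell 1.67-fold. The list median was -0.32 (camera adjusted p = 0.00059; adjusted p = 0.58 with an estimated correlation), with 9 lower and 2 higher adjusted over the list alone. The Gapdh 3' to 5' ratio was 1.11, 1.94 and 2.58 on these arrays, and the myeloid marker median was 0.39. Erythroid and platelet markers had 1 of 14 higher, Hbb-b2 at 1.63-fold, and a median of 0.135 (adjusted p = 0.0458; adjusted p = 0.58 with an estimated correlation). That call was also lost without the filter and with both other scalings, and the 3' to 5' ratios and myeloid markers were higher on the same arrays.

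B cell markers had 2 of 17 higher and 1 lower, H2-Aa and Bank1 rising 1.60-fold and 1.62-fold and Fcmr falling 1.98-fold (adjusted p = 0.126). With list symbols matched exactly, which leaves out Fcmr, the B cell list passed (adjusted p = 0.0419); the matching was settled after that value had been seen. Plasma cell markers had 3 of 10 lower, led by Creld2 at 1.62-fold (adjusted p = 0.264). Among CD8 and NK lineage markers 3 of 11 were higher and 1 lower: the NK receptor gene Klra8 rose 2.27-fold and Cd8b1 fell 2.27-fold. Their median was -0.11 and their mean 0.011, with the camera direction up (adjusted p = 0.404). The median was -0.18 without the second Rptor-null array, -0.036 without the first and 0.075 with the 60th percentile filter. Adjusted over the list alone, higher and lower counts were 1 and 0 for erythroid, 4 and 2 for B cell, 0 and 3 for plasma cell and 3 and 4 for CD8 and NK markers.

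**Figure D3:**
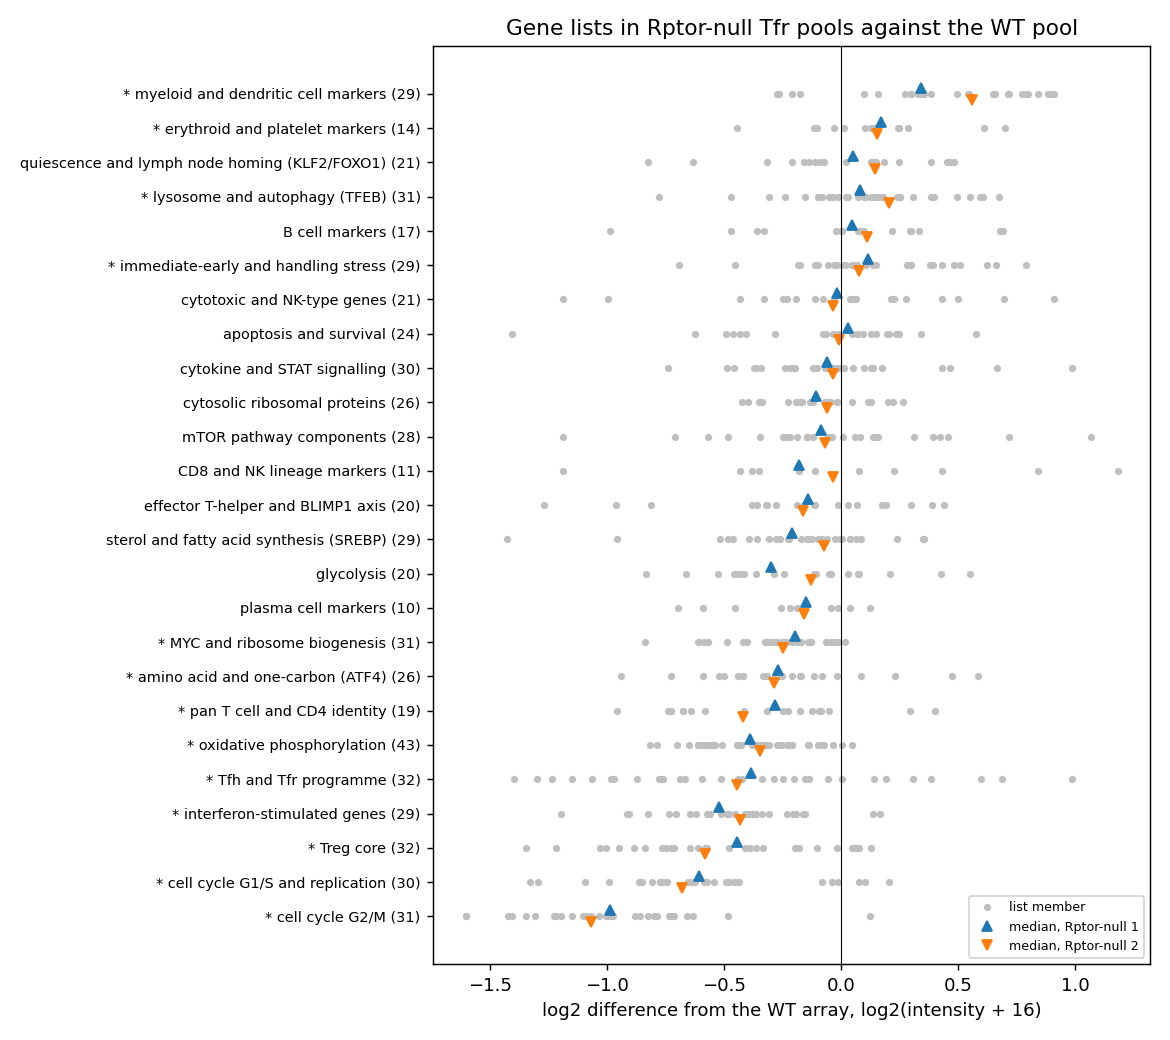
Log2 difference from the WT array for each of the 25 gene lists, with members as grey points, the median of each Rptor-null array as a triangle, the number tested in parentheses and an asterisk where the camera adjusted p with the preset correlation was under 0.05. The G2/M list lies lowest with a median of -1.004, and the myeloid and dendritic cell markers lie highest at 0.39.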

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

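The values here were examined after the main results had been seen, and no explanation was tested for them. Control probe sets, which the comparisons leave out, were brighter on both Rptor-null arrays than on the WT array. The 18 hybridisation control probe sets had a median log2 difference of 2.039, and the 24 poly-A RNA control probe sets one of 2.672. The 3 probe sets for 18S rRNA had a median of 1.49. The 3' to 5' ratios of the spiked transcripts were also higher in the Rptor-null arrays, at 13.7, 19.0 and 26.8 for dap, 4.19, 5.10 and 6.06 for lys, 3.14, 5.65 and 11.1 for phe and 12.5, 40.4 and 54.1 for thr, each as WT and then the 2 Rptor-null arrays.

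Among the 4642 kept probe sets that name no gene or several, 25 were at least 2-fold higher and 25 at least 2-fold lower than WT in both Rptor-null arrays.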

How the results depend on the processing

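Exact symbol matching and leaving out cross-matching probe sets were chosen after seeing the data, and all other settings before. Over 25 lists and these settings, 254 of 300 list results kept their direction and side of the threshold, or moved by less than the spread between the Rptor-null arrays. Over the 126 named genes this held for 1430 of 1502, with 53 calls lost, 14 gained and 5 directions turned. For a gene with 1 Rptor-null array left out, the move is under that spread by construction. Only a turned direction could then count against it, so these results say little about stability. No paired analysis was possible because the WT group has 1 array. The WT array has no replicate, so its own error limits every comparison, and with 1 Rptor-null array left out there was no test. Unless a reason is given, the cause was not tested.

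The counts of calls were 877 higher after median centring, 695 lower after quantile normalization (1159 calls shared with the reported ones), and 300 higher and 770 lower without a variance trend. With every probe set tested, 754 were higher. Genes at least 2-fold higher and lower were 31 and 36 with a pseudocount of 64, which shrinks folds, and 79 and 47 after quantile normalization. They were 106 and 177 over every probe set, with more features counted, and 27 were higher with the mean of a gene's probe sets. With 1 Rptor-null array, which drops the need for both to pass, the counts were 65 to 117 higher and 126 lower with either.

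With an estimated correlation, each of the 13 list calls was lost (adjusted p = 0.58) while medians stayed as they were by construction: -0.43 for Tfh and Tfr, -0.53 for Treg core, -0.27 for amino acid, -0.63 for G1/S, -1.004 for G2/M, -0.24 for MYC, -0.35 for oxidative phosphorylation, 0.13 for lysosome, -0.45 for interferon, 0.066 for immediate-early, 0.39 for myeloid, 0.135 for erythroid and -0.32 for pan T cell genes. Among level-matched random lists, the 9 lower lists lay between percentiles 0 and 4.63 and the 4 higher ones between 96.0 and 100. Lists without a call also lay high, with quiescence at 99.91, cytotoxic at 96.59 and apoptosis at 95.98, so these percentiles do not single out the called lists. The erythroid call was lost without the filter (0.127), after quantile normalization (0.164) and after median centring (0.188). The quiescence list passed with the 60th percentile filter (0.1285, adjusted p = 0.0482) and after quantile normalization (0.174, adjusted p = 0.0216). The B cell list passed with symbols matched exactly (0.0787, adjusted p = 0.0419), which leaves out Fcmr.

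Directions turned for lists that had no call. The mTOR list was 0.0090 after quantile normalization, and the cytokine list 0.067 after quantile normalization and 0.0087 after median centring. The cytotoxic list was -0.028 with the mean of probe sets, and the CD8 and NK list 0.075 with the 60th percentile filter. The apoptosis list was -0.010 without the filter, -0.018 with the mean of probe sets and -0.0066 without cross-matching probe sets. Among genes, Stat3 was 0.069 after quantile normalization, and with the mean of probe sets Pik3cd was -0.029, Rps9 0.047 and Rpl27 0.019.

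Leaving out each Rptor-null replicate in turn gave list medians of -0.444 to -0.385 for Tfh and Tfr, -0.160 to -0.14 for effector, -0.036 to -0.016 for cytotoxic, 0.051 to 0.143 for quiescence, -0.083 to -0.066 for mTOR and -1.07 to -0.987 for G2/M genes. The ranges were -0.247 to -0.197 for MYC, -0.105 to -0.058 for ribosomal protein, -0.39 to -0.348 for oxidative phosphorylation, -0.0088 to 0.031 for apoptosis, -0.521 to -0.429 for interferon and 0.078 to 0.114 for immediate-early genes. They were -0.156 to -0.148 for plasma cell, 0.344 to 0.560 for myeloid, 0.155 to 0.171 for erythroid and -0.417 to -0.281 for pan T cell genes. For the other lists they were -0.583 to -0.444 for Treg core, -0.678 to -0.606 for G1/S, -0.285 to -0.268 for amino acid, -0.299 to -0.126 for glycolysis, -0.209 to -0.074 for sterol, 0.081 to 0.203 for lysosome, -0.058 to -0.034 for cytokine, 0.045 to 0.109 for B cell and -0.181 to -0.036 for CD8 and NK genes. Rptor ranged from -0.048 to 0.17.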

Other observations

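All tests in this part except those of amplified RNA length and of the genes next to Rptor were chosen only after the result was seen, as were its marker lists. Markers of splenic red pulp macrophages and of basophils were counted without a test of the lists as groups. Of 23 macrophage markers 14 were higher, 0 lower and 9 not past the test, with a median log2 difference of 0.72. The iron exporter Slc40a1 rose from 3680 to 9305 ± 499 (2.52-fold), the engulfment receptor Mertk 2.34-fold, Vcam1 2.29-fold and Cd5l 2.16-fold. Of 17 basophil and mast cell markers 11 were higher, 1 lower and 5 not past the test, with a median of 0.80, and among them Hdc, which makes histamine, rose 2.71-fold and the IgE receptor chain Fcer1a 2.38-fold.

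Neutrophil markers had 1 higher and 1 lower of 13 and a median of -0.19, with S100a8 at 7644 in WT and 8177 ± 22.6 in Rptor-null pools. Conventional dendritic cell markers had 1 higher and 1 lower of 8 (median 0.33), and plasmacytoid dendritic cell markers 0 higher and 1 lower of 9 (median 0.24).

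For the higher myeloid markers, a candidate explanation is that the Rptor-null pools held more macrophages and basophils. Lineage depletion and the CD4 gate were meant to remove such cells, yet Csf1r and Lyz2 also read high in the WT pool. Of the 40 markers 36, or 90%, were higher in both Rptor-null arrays, with a median of 0.749. Because 8 also stand in the preset myeloid list and 2 basophil markers were among the 10 largest increases, the count was repeated on the 29 markers outside that list and the named genes, of which 25 were higher in both (median 0.768). Abundant genes such as Lyz2 (log2 difference 0.16) and Apoe (-0.13) did not rise alike, and which cells expressed them was not tested. Their high levels in WT do not by themselves account for this, since Csf1r and Slc40a1 also read high there and rose. The preset myeloid list exceeded the preset B cell list by 0.31 (permutation p = 0.0133). That permutation shuffled genes as if independent and carries no error between pools. The B cell list was also mixed, with Fcmr at -0.99 and Cd22 at -0.47 but H2-Aa at 0.68 and Bank1 at 0.69. Macrophage and basophil markers had medians of 0.72 and 0.80 (SD 0.45 and 0.56). Neutrophil markers had one of -0.19 (SD 0.42), with 5 of 13 above WT in both arrays. For these lists, the medians argue against a lower share of T cells that raised every other cell type alike. They carry no error between pools. Expression of these genes by Rptor-null Tfr cells themselves stays open as untested.

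For the lower cell cycle genes, the cell cycle lists fell beyond the T cell identity list (difference -0.4806, permutation p = 0.00021). That permutation shuffled genes as if independent and carries no error between pools. Of the 19 T cell identity genes 9 were lower and 1 higher, and they spread widely (SD 0.37). Cd3g stood at -0.957, Lat at -0.738 and Cd44 at 0.294, so the list median is no clear measure of the T cell share. In the G2/M list 11 of 31 members were at least 2-fold lower in both arrays, against 0 of 19 T cell identity genes. The medians were -1.004 (SD 0.35) and -0.32. For the G2/M list these values argue against a lower share of T cells alone, although Cd3g stood near its median. The G1/S median of -0.63 lay within the spread of the T cell identity genes, so for that list this explanation is not excluded. Shorter amplified RNA cannot be told apart from a change in the cells. In 36 genes with several probe sets the least-lowered probe set had a median of -0.3086 (95% bootstrap interval -0.601 to -0.0867), between the bounds set beforehand, against 0.101 in other genes. Less division of Tfr cells without mTORC1 stays open as a biological explanation that was not tested.

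A lower share of T cells in the Rptor-null pools may account for the lower medians of the Treg core and Tfh and Tfr lists. Beyond the T cell identity list, the Tfh and Tfr programme differed by -0.1146 (permutation p = 0.699), the Treg core by -0.2108 (permutation p = 0.301) and both together by -0.1441 (permutation p = 0.558). The Treg core value lies past the bound of 0.2 but within the spread of the genes, so for that list a lower T cell share cannot be told apart from a further fall. A p that misses the threshold does not show that the lists moved alike. Medians also say little about single members. In both arrays 3 of 32 Tfh and Tfr members and 2 of 32 Treg core members were at least 2-fold lower. Of the 19 T cell identity genes 0 were. In the Tfh and Tfr list 3 members were higher, and Bcl6 stood at -0.15. Single members were not tested against the T cell share. The loss of Rptor stays open as an explanation.

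The lower Xist may reflect more male mice in the Rptor-null pools. Of the Y-linked genes tested, 3 of 3 were higher in both Rptor-null arrays (median 0.33), and 1, Eif2s3y, passed the test (log2 difference 0.59, adjusted p = 0.0253). Genes next to Rptor were no more often past the test than others: 28 of the nearest 200, or 14%, against 15.03%, a ratio of 0.9316 (Fisher's exact p = 0.765). As a group these neighbours held no excess of calls. A share over 200 genes cannot show whether a few genes near Rptor were carried along with the targeted allele.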
